A study of Homo sapiens with 12 samples.

How the data were processed

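Messenger RNA was sequenced from 12 libraries of hTERT RPE-1 cells, a human retinal pigment epithelial line immortalised with telomerase. Per the labels, 4 clonal stable lines were compared, 2 of which overexpressed the red fluorescent protein mCherry (mCherry_3 and mCherry_4) and 2 a fusion of mCherry with lamin B1 (LmnB1_6 and LmnB1_16). Each clone contributed 3 libraries described as biological replicates, and every culture had received doxycycline at 0.05 ug/mL for 24 hours. Per the labels' protocols, RNA was extracted with Trizol and a column kit, and an outside provider made the libraries. Strand, read length and fragment length are not given in the sources used here, so reads of overlapping genes on opposite strands are not told apart here.

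The authors deposited a gene-level quantification for each library with estimated counts of fragments, TPM (transcript abundance scaled by effective length), gene length and effective length, per the file headers. The submitters' processing notes name STAR, Salmon and DESeq2, without versions, and the genome build GRCh38 (hg38). The estimated counts that the authors deposited are not normalized. Between 31.3% and 32.6% of the genes detected in a library had an estimated count that was not whole, so counts were rounded to whole numbers before any count test. The TPM that the authors deposited are scaled by effective length and were used only as an alternative. The files hold 60708 versioned Ensembl gene identifiers, of which 58396 matched the GENCODE 29 annotation of GRCh38 without their version and 60463 had a symbol. The annotation release the authors counted on is not given in the sources used here. Gene positions come from GENCODE 29.

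Total estimated counts ran from 20.6 to 29.5 M per library, and 14178 to 14927 genes had at least 10 counts. Genes were tested where edgeR's filterByExpr, grouped by clone, kept them (minimum count 10, minimum total 15). This left 15388 genes, 12774 of them protein coding, which held at least 99.9% of each library's counts. Counts were scaled with TMM factors (0.948 to 1.06) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. The construct comparison set the 6 LmnB1 libraries against the 6 mCherry libraries. Another model had the 4 clones as groups and gave each LmnB1 clone against the mean of both mCherry clones, the contrasts within a construct, and the 4 contrasts of an LmnB1 clone with an mCherry clone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and core genes were those called in the same direction in all 4 of the last contrasts. Standard errors are the log2 fold change over the square root of the quasi-likelihood F statistic. The p-values measure the spread between these libraries. Libraries of a clone are not independent samples of a construct, which is represented by 2 clones. The biological coefficient of variation was 0.262 in the construct fit and 0.0842 in the fit with clones as groups. The core count, the count of 6 against 6 libraries and the count of gene lists called were repeated for both other ways of pairing the 4 clones.

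The comparisons, the alternatives, the rule for named genes and 26 gene lists were fixed before the data were examined. Of these lists, 23 had at least 5 tested members. They were tested with camera in limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01 between genes and adjustment over the lists, and again with an estimated correlation and with fry. Chromosomes were tested as sets in the same way, and a chromosome was called at an adjusted p under 0.05 and a median log2 fold change of at least 0.1 either way. The rule for named genes takes LMNB1, then the 12 core protein-coding genes with the largest rise and the 12 with the largest fall in the construct comparison at a mean of at least 1 CPM. It adds up to 4 called members of each list with the smallest adjusted p (the 2 most abundant where none was called), and the 5 protein-coding genes with the largest rise and fall between the clones of each construct. A few genes that the rule takes are not reported here. Apart from members of the HOX list, genes outside the rule are marked as chosen after their values were seen. Levels are CPM, counts scaled to library size with TMM factors. For a gene with 0 counts in a clone, the bound on a fold uses 3 counts over the libraries of that clone, which covers counting error only.

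The tests were checked on simulated counts for the 15388 genes, drawn from the real means and library sizes with the spread within clones, so differences between clones of a construct are not in them. In the construct comparison 80.6% of the 67 genes changed 1.5-fold, 80.6% of the 67 changed 2-fold and 92.4% of the 66 changed 4-fold were recovered, with 10 false calls. In the contrast of the mCherry clones 55.2% of the 67 genes changed 1.5-fold, 74.6% of the 67 changed 2-fold and 89.4% of the 66 changed 4-fold were recovered, with 5 false calls. Alternatives were size factors by relative log expression, other filters on low counts, DESeq2 1.42.0, offsets for transcript length, the replicate number as a covariate, counts summed per clone, clone as a random effect in limma, log2 TPM, and leaving out each library or clone. GC content and length of the longest GENCODE 29 transcript and the number of protein-coding genes within 1 Mb either side were known for 98.9% of the tested genes. Figures were drawn with matplotlib 3.10.9. No library was left out of the main comparisons.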

Results

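The 12 libraries came from 4 clonal hTERT RPE-1 lines with 3 libraries each. In 2 lines the construct was mCherry alone, the control, and in 2 it was mCherry fused to lamin B1, a filament protein of the nuclear lamina. Total estimated counts were 25.1, 26.2 and 25.4 M in mCherry_3, 23.04, 25.3 and 24.3 M in mCherry_4, 23.8, 20.6 and 29.5 M in LmnB1_6 and 20.8, 20.8 and 27.4 M in LmnB1_16. Mitochondrial transcripts took 2.06% to 2.69% of the counts and the 10 most abundant genes 4.57% to 6.47%. No pair of libraries matched within sampling noise, since the chi-square per degree of freedom was at least 4.03 for libraries of the same clone. Levels are CPM (counts scaled to library size), as mean ± SD over the 3 libraries of a clone (n = 3) unless another n is given.

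LMNB1 (ENSG00000113368.12, chromosome 5, 126776623 to 126837020, plus strand, GRCh38), the gene that the construct carries, was measured first, since it checks the labels. It stood at 84.98 ± 7.12 in mCherry_3, 161 ± 7.29 in mCherry_4, 3976 ± 164 in LmnB1_6 and 3374 ± 273 in LmnB1_16. By construct this was 123 ± 42.4 against 3675 ± 386 (SD, n = 6; log2 fold change 4.90, SE 0.23, edgeR adjusted p = 1.25e-07). LMNB1 was higher in each of the 6 LmnB1 libraries than in any mCherry library. Reads of the construct and of the endogenous gene are not separated in gene-level counts. LMNB1 was 1.90-fold higher in mCherry_4 than in mCherry_3 (edgeR adjusted p = 4.79e-08) and 1.18-fold higher in LmnB1_6 than in LmnB1_16 (edgeR adjusted p = 0.0117). The deposited effective length of LMNB1 was 2530.3 ± 80.6 bases in the mCherry libraries and 1013 ± 17.1 bases in the LmnB1 libraries (SD, n = 6). The deposited TPM of LMNB1, which are scaled by it, rose from 71.6 ± 23.5 to 5216 ± 583 (SD, n = 6). Of the 15388 tested genes, 6 had a larger fall of effective length than LMNB1 between the constructs.

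**Figure D1:**
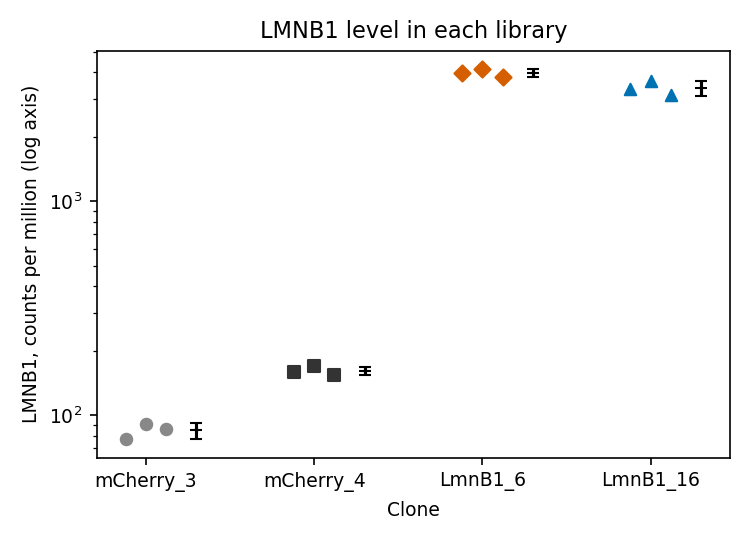
LMNB1 in CPM (log axis) in each of the 12 libraries, by clone, with the mean and SD (n = 3) beside the points. The LmnB1 clones lie at means of 3976 and 3374 and the mCherry clones at 84.98 and 161.

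Across all tested genes the libraries grouped by clone. PC1, the first principal component, held 45.6% of the variance and set LmnB1_6 apart from the other 3 clones. PC2 held 21.03% and ran from mCherry_3 to LmnB1_16, and PC3 held 12.5% and ran from mCherry_4 to LmnB1_16. None of these 3 components placed both LmnB1 clones on the opposite side from both mCherry clones.

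**Figure D2:**
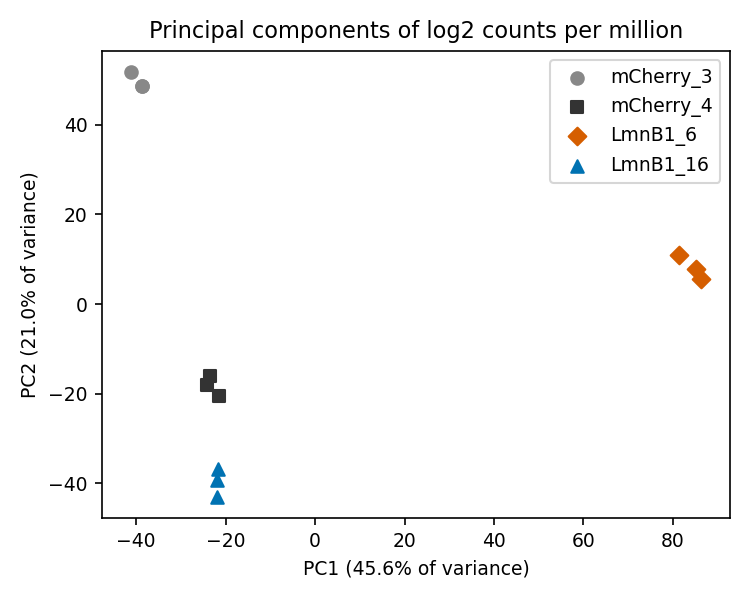
The first and second principal components of log2 CPM for the 12 libraries, with 45.6% and 21.03% of the variance. Libraries of a clone lie together, and LmnB1_6 lies apart on PC1.

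The construct comparison asks which genes differ between cells with the lamin B1 fusion and cells with mCherry. ZNF185 (ENSG00000147394.18, chromosome X), which encodes an actin-associated LIM domain protein, rose from 1.89 ± 0.555 and 2.88 ± 0.782 in mCherry_3 and mCherry_4 to 125 ± 3.36 and 87.3 ± 2.12 in LmnB1_6 and LmnB1_16 (log2 fold change 5.48, SE 0.23, edgeR adjusted p = 3.54e-08). POGLUT3, an O-glucosyltransferase gene, rose from 0.759 ± 0.388 and 2.49 ± 0.370 to 34.5 ± 3.36 and 61.6 ± 6.57, and BGN, which encodes the matrix proteoglycan biglycan, from 1.07 ± 0.129 and 4.84 ± 0.545 to 50.4 ± 4.72 and 63.03 ± 4.13. HSPB8 (ENSG00000152137.8, chromosome 12), a small heat shock protein gene, stood at 43.9 ± 1.84 and 16.5 ± 0.210 in the mCherry clones (4713 counts) and had 1 count in the 6 LmnB1 libraries. MAOA (ENSG00000189221.10, chromosome X), which encodes monoamine oxidase A, fell from 20.5 ± 2.17 and 13.2 ± 2.38 to 0.0499 ± 0.0503 and 0.110 ± 0.0971 (log2 fold change -7.57, SE 0.43, edgeR adjusted p = 7.21e-07).

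Other core genes of the rule that rose were APBA2 (0 and 0.282 in the mCherry clones, 20.1 and 7.04 in LmnB1_6 and LmnB1_16), ZSCAN18 (1 count in all mCherry libraries, 4.40 and 1.62 in the LmnB1 clones), TNFSF12, CKB, ZNF331, RNF125, SNAP25 and IL17RD. TNFSF12, a cytokine gene, shares exons with a readthrough transcript and is uncertain. RNF125, SNAP25 and IL17RD were higher in LmnB1_6 than in LmnB1_16. IL17RD, which encodes an inhibitor of growth factor signalling, was at 6.42 ± 0.575 and 8.12 ± 0.708 in the mCherry clones, 193 ± 13.4 in LmnB1_6 and 14.4 ± 1.07 in LmnB1_16. Falls were also called for NXPH2, the cytochrome P450 gene CYP2J2 (4.68 and 2.52 to 0.115 and 0.0570), ADGRV1, LY6E, PLEKHA6 (14.1 and 22.6 to 0.0470 and 1.53), ZNF512 and SLC26A11. PCDHA12 and PCDHA6 fell as well, and both are uncertain because genes of the protocadherin alpha cluster share their last exons. PCDHA12 had 0 counts in the LmnB1 libraries and was at least 109-fold higher in the mCherry libraries (2.31 CPM, n = 6, against 3 counts over all LmnB1 libraries). DPP7 (ENSG00000176978.14, chromosome 9), a lysosomal peptidase gene chosen after its values were seen because its p was the smallest, fell from 66.9 ± 0.367 and 59.96 ± 4.67 to 8.24 ± 0.848 and 8.18 ± 0.337 (log2 fold change -2.95, SE 0.07, edgeR adjusted p = 8.53e-11).

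Of 15388 genes, 2743 were called between the constructs, 1320 higher and 1423 lower in the LmnB1 libraries, and 587 of them changed at least 2-fold (293 higher, 294 lower). With counts summed per clone, edgeR called 0 genes (642 at an unadjusted p under 0.05, smallest adjusted p = 0.261, with 2 clones against 2), and limma with clone as a random effect called 163. The summed test did not call LMNB1 either (edgeR adjusted p = 0.778). The count was 647 without clone mCherry_3, 1263 without LmnB1_6, 4958 without mCherry_4 and 4808 without LmnB1_16. It was 1493, 1495 and 1392 without replicate 1, 2 or 3 of mCherry_3, and 1567, 1527 and 1828 without those of LmnB1_6.

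Core genes, which separate each LmnB1 clone from each mCherry clone, numbered 720, with 272 higher and 448 lower in the LmnB1 clones. They included UHRF1, TRIM28, DNMT3B and EZH2 of the heterochromatin list and MCM5, UNG, POLD1 and MCM7 of the replication list, all higher, and CDKN1A, CCN1 and F3, all lower. For comparison, the pairing of mCherry_4 and LmnB1_16 against mCherry_3 and LmnB1_6 gave 884 such genes, and that of mCherry_4 and LmnB1_6 against mCherry_3 and LmnB1_16 gave 314. In the test of 6 against 6 libraries the 3 pairings called 2743, 1874 and 555 genes. Clone means separated the pairs without overlap for 40.5%, 33.5% and 25.9% of the genes, where symmetry gives 33.3%. In the same order, 183, 221 and 155 genes differed at least 2-fold in all 4 contrasts. Genes under 0.5 CPM in both clones of a pair and at 1 or more in both others numbered 27, 33 and 20. At 5 or more CPM in both others they numbered 3, 2 and 3.

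**Figure D3:**
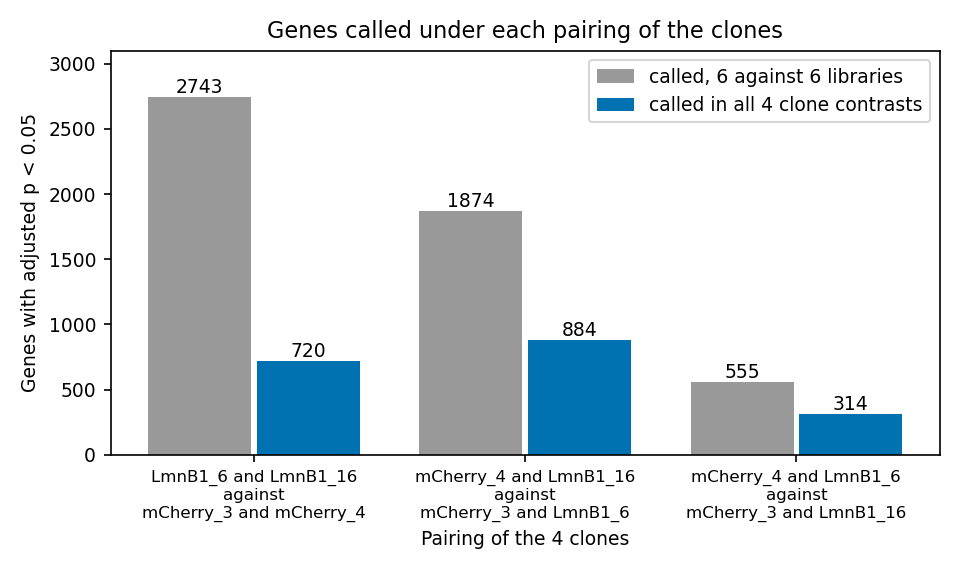
The number of genes called at an adjusted p under 0.05 for each pairing of the 4 clones, in the test of 6 against 6 libraries (grey bars) and in all 4 clone contrasts (blue bars). The pairing by construct gives 2743 and 720 genes, and the others give 1874 and 884, and 555 and 314.

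Genes of DNA replication and the G1/S transition were higher in the LmnB1 libraries, where 15 of 32 rose and 0 fell (21 and 0 adjusted over the list alone; median 0.32, camera adjusted p = 8.72e-09, adjusted p = 0.763 with an estimated correlation). MCM7, a subunit of the replicative helicase, was at 212 ± 28.3 and 312 ± 9.60 in mCherry_3 and mCherry_4 and 373 ± 24.9 and 382 ± 5.17 in LmnB1_6 and LmnB1_16. Of the mitotic genes 3 of 32 rose, which were CDC25C, KIF2C and TTK, and 0 fell (0 and 0 adjusted over the list alone; median 0.51, camera adjusted p = 7.13e-09, adjusted p = 0.763 with an estimated correlation). Clone mCherry_3 stood apart in these lists. All 32 mitotic genes were lower there than in mCherry_4, and against mCherry_4 alone the median log2 fold change was 0.05 in LmnB1_6 (5 higher, 4 lower) and 0.11 in LmnB1_16 (4 higher, 0 lower). For the replication list these medians were 0.06 (8 higher, 1 lower) and 0.19 (11 higher, 0 lower). With the preset correlation and without mCherry_3 the replication list was called (3 higher, 0 lower, median 0.16, camera adjusted p = 0.000142), and so was the mitotic list (0 higher, 0 lower, median 0.09, camera adjusted p = 0.0392). With an estimated correlation and without mCherry_3 neither was called (camera adjusted p = 0.769 and 0.769). In all, 8 lists were called with the preset correlation, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 with fry, which was the heterochromatin list (fry adjusted p = 0.000902). Both other pairings of the 4 clones called more lists with the preset correlation, 11 and 12. The replication and nuclear pore lists were called in both of these pairings, and the heterochromatin list in neither.

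Of the heterochromatin and Polycomb genes 13 of 34 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.14, camera adjusted p = 0.000115, adjusted p = 0.356 with an estimated correlation). UHRF1, which encodes a reader of hemimethylated DNA, went from 174 ± 12.3 and 209 ± 6.93 to 284 ± 9.69 and 279 ± 2.35, and EZH2, the Polycomb methyltransferase, from 45.7 ± 2.68 and 60.8 ± 1.63 to 74.3 ± 2.80 and 74.7 ± 5.57. TRIM28, a corepressor gene, rose from 431 ± 18.1 and 504 ± 23.8 to 618 ± 25.01 and 577 ± 6.56 (log2 fold change 0.35, SE 0.07, edgeR adjusted p = 0.00595). Without mCherry_3 this list was also called (7 higher, 0 lower, median 0.18, camera adjusted p = 2.70e-06), but not with an estimated correlation (adjusted p = 0.250). Nuclear pore genes rose for 9 of 29 members and fell for 1 (14 and 1 adjusted over the list alone; median 0.21, camera adjusted p = 6.48e-06, adjusted p = 0.763 with an estimated correlation), and their mean was -0.06. SEH1L, NUP188 and AAAS had log2 fold changes of 0.26, 0.22 and 0.31. The member that fell was NUP210, which was at 97.3 ± 3.34 in mCherry_4 and at 0.273, 0.521 and 0 in mCherry_3, LmnB1_6 and LmnB1_16. Without mCherry_3 the pore list was not called (camera adjusted p = 0.0503).

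Among the YAP/TEAD targets 7 of 23 fell and 1 rose (9 and 2 adjusted over the list alone; median -0.24, camera adjusted p = 0.0417, adjusted p = 0.763 with an estimated correlation). CCN1, which encodes a secreted matricellular protein, fell from 1429.6 ± 80.97 and 1216 ± 58.05 to 574 ± 66.8 and 976 ± 71.6, and F3, which encodes tissue factor, from 331 ± 73.8 and 465 ± 74.6 to 94.9 ± 8.78 and 242 ± 27.4. ARHGEF17 and RBMS3 had log2 fold changes of -0.30 and -0.51. This list was also called without mCherry_3 (0 higher, 3 lower, median -0.30, camera adjusted p = 0.000690), but not with an estimated correlation (adjusted p = 0.250). It was higher in mCherry_4 than in mCherry_3 (median 0.25, camera adjusted p = 0.00563). Against mCherry_3 alone it was not called in LmnB1_6 (median -0.20, camera adjusted p = 0.259) or LmnB1_16 (median -0.06, camera adjusted p = 0.735). Of the interferon-stimulated genes 5 of 30 fell and 0 rose (5 and 0 adjusted over the list alone; median -0.35, camera adjusted p = 0.0152, adjusted p = 0.766 with an estimated correlation), HERC5, ISG15 and PARP9 among them. Of the MHC class I and antigen processing genes 1 of 15 fell, HLA-E, whose family shares sequence and which is uncertain (1 adjusted over the list alone; median -0.20, camera adjusted p = 0.0152, adjusted p = 0.766 with an estimated correlation). This list was low in LmnB1_6 alone. Its mean log2 level relative to all libraries was 0.20, 0.13, -0.61 and 0.27 in mCherry_3, mCherry_4, LmnB1_6 and LmnB1_16. Of the mitochondrial respiratory chain genes 1 of 35 fell, NDUFB5 (1 adjusted over the list alone; median -0.09, camera adjusted p = 0.0159, adjusted p = 0.766 with an estimated correlation). Without mCherry_3 these last 3 lists were not called (camera adjusted p = 0.432, 0.0503 and 0.285).

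The other 15 tested lists had camera adjusted p from 0.0891 to 0.811. Of the lamins and inner nuclear membrane proteins, a list that holds LMNB1, 3 of 24 rose and 2 fell (6 and 2 adjusted over the list alone). TMPO, which encodes the lamina-associated polypeptide 2 proteins, had a log2 fold change of 0.66, and SYNE1 and SUN1, of the complex that links the nucleus to the cytoskeleton, had -0.94 and -0.18. Of the p53 targets 0 of 26 rose and 4 fell (0 and 4 adjusted over the list alone), which were CDKN1A (315 ± 43.1 and 309 ± 9.93 to 224 ± 54.3 and 184 ± 27.1), TNFRSF10B, GADD45A and PLK3. Of the senescence secretory genes 1 of 20 rose, LIF (74.9 ± 12.5 and 106 ± 1.97 to 175 ± 15.7 and 170.2 ± 19.96), and 2 fell, IGFBP7 among them (1 and 2 adjusted over the list alone). The median of this list was 0.12 while its test pointed down. Of the matrix genes 5 of 28 rose and 1 fell (6 and 1 adjusted over the list alone), with VCAN (versican) at 191 ± 20.6 and 619 ± 64.9 against 2875 ± 219 and 1143 ± 215, LAMB1 higher and HSPG2 lower. Of the epithelial and mesenchymal genes 3 of 19 rose, among them SNAI2 and ZEB2, and 4 fell, among them the desmosomal gene DSP and the keratin gene KRT8 (8 and 5 adjusted over the list alone). Of the TGF-beta targets 4 of 18 rose, among them PMEPA1, ID2 and LTBP2, and 1 fell (4 and 1 adjusted over the list alone). PMEPA1 was at 7.20, 18.2, 266 and 16.1 in mCherry_3, mCherry_4, LmnB1_6 and LmnB1_16. Against the mCherry clones, ID2, LTBP2 and SNAI2 were called in LmnB1_6 but not in LmnB1_16, where their log2 fold changes were -0.04, -0.07 and 0.44.

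Of the unfolded protein and ATF4 response genes 3 of 25 rose (SLC7A11, PHGDH and SDF2L1) and 0 fell (1 and 0 adjusted over the list alone). Of the cholesterol synthesis genes 0 of 24 rose and 3 fell (LSS, STARD4 and TM7SF2; 0 and 5 adjusted over the list alone). In the glycolysis and hypoxia list NDRG1 rose and HK1 fell, of 27 (0 and 0 adjusted over the list alone). No mitochondrially encoded gene of 13 was called (0 and 0 adjusted over the list alone), with log2 fold changes of 0.12 for MT-CO1 and 0.08 for MT-ND4. Of the histone genes 3 of 15 rose, with MACROH2A1 among them, and 6 fell, with H2BC21, H2BC12 and H4C8 among them (6 and 6 adjusted over the list alone), and the replicated copies are uncertain because they share sequence. Of the clustered protocadherins, uncertain for the same reason, PCDHB14 rose and PCDHA6, PCDHA7 and PCDHA12 fell, of 28 (1 and 3 adjusted over the list alone), and the median of 0.36 and the mean of -0.19 differ in sign. HOXB3 was the HOX gene called, of 8 (1 and 0 adjusted over the list alone). Of 12 pigment epithelium genes RDH10 and SERPINF1 rose and RDH5 and LRAT fell (3 and 2 adjusted over the list alone). RDH10, a retinol dehydrogenase gene, went from 14.98 ± 1.14 and 14.02 ± 0.615 to 33.3 ± 0.934 and 27.5 ± 2.03 (log2 fold change 1.07, SE 0.08, edgeR adjusted p = 1.36e-05). Of 8 neuronal and glial markers SNAP25, MAP2 and TUBB3 rose (4 and 0 adjusted over the list alone). None of the measured leukocyte (2), endothelial (4) or muscle (3) markers was called (0 and 0 adjusted over each list alone). In the order mCherry_3, mCherry_4, LmnB1_6 and LmnB1_16, CD68 was at 83.2, 64.5, 42.3 and 74.05, CSF1R at 1.37, 5.54, 1.58 and 4.12, TIE1 at 15.04, 3.90, 5.17 and 7.20, ESAM at 0.844, 1.26, 0.883 and 0.949, TNNT1 at 138, 55.3, 29.5 and 88.6, and DES at 1.72, 0.341, 0.594 and 0.273 CPM.

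Of 87 genes called between the constructs that the rule for named genes takes from them or from the lists, LMNB1 included, 37 were not core genes. For 8 of them the change was called in LmnB1_6 and not in LmnB1_16, each against the mCherry clones. Their log2 fold changes in LmnB1_6 and LmnB1_16 were 4.39 and 0.44 for SNAI2, 2.80 and -0.04 for ID2, 2.46 and -0.07 for LTBP2, 1.11 and 0.19 for NDRG1, 1.78 and 0.27 for PCDHB14, 4.99 and -0.23 for HOXB3, -0.67 and -0.36 for RDH5, and 2.12 and 0.86 for SERPINF1.

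**Figure D4:**
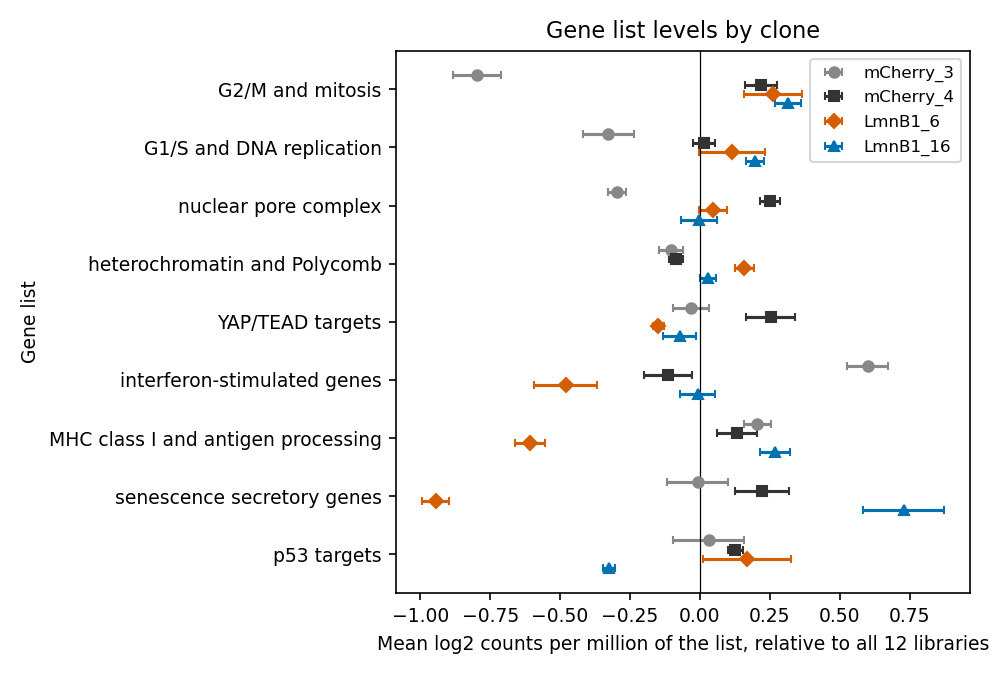
Mean log2 CPM of the tested members of 9 gene lists in each clone, relative to the mean of all 12 libraries, with the SD over 3 libraries. The mitotic list is lowest in mCherry_3, and the MHC class I and senescence secretory lists are lowest in LmnB1_6.

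Each LmnB1 clone was set against the mean of the mCherry clones, which asks whether each shows a change by itself. In LmnB1_6 the HOX genes, developmental transcription factors, rose for 7 of 8 tested members and fell for 0, all of them in the HOXB cluster (median 3.95, camera adjusted p = 4.55e-07, adjusted p = 0.0116 with an estimated correlation). HOXB3 was at 103 ± 3.58 in LmnB1_6 and at 5.83 ± 0.566, 1.80 ± 0.309 and 2.78 ± 0.221 in mCherry_3, mCherry_4 and LmnB1_16. Also in LmnB1_6, 14 of 15 MHC class I and antigen processing genes fell (median -0.61, camera adjusted p = 4.44e-07, adjusted p = 0.0411 with an estimated correlation), 12 of 20 senescence secretory genes fell and 3 rose (median -1.30, camera adjusted p = 0.00241, adjusted p = 0.174 with an estimated correlation), and 10 of 18 TGF-beta targets rose and 3 fell (median 0.55, camera adjusted p = 0.000851, adjusted p = 0.0411 with an estimated correlation). In LmnB1_16, 15 of 26 p53 targets fell and 1 rose (median -0.32, camera adjusted p = 3.57e-05, adjusted p = 0.255 with an estimated correlation), and 9 of 20 senescence secretory genes rose and 4 fell (median 0.57, camera adjusted p = 0.00373, adjusted p = 0.255 with an estimated correlation). In all, 7534 genes were called in LmnB1_6 (3747 higher, 3787 lower) and 5195 in LmnB1_16 (2654 higher, 2541 lower). Against mCherry_4 alone LmnB1_16 had 2411.

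Both LmnB1 clones were compared with the same mCherry libraries, so their fold changes share chance values. The clones shared 1594 genes called higher and 1428 called lower, against 646 and 625 for independent lists of those sizes, and 668 genes were called in opposite directions. Across genes, which are not independent replicates, the fold changes had a correlation of 0.236 and a covariance of 0.209. Simulated groups, drawn from the mean CPM of both mCherry clones with the spread within clones, were set against the same libraries. Over 20 draws they gave a mean correlation of 0.544, a covariance of 0.0547 and 66 shared calls higher and 0 lower. The contrast averages the mCherry clones on the log scale, so a gene that differs between them tends to come out higher in both simulated groups. The draws also hold no differences between the LmnB1 clones. They therefore cannot show how many shared calls arise without a change. With a separate mCherry clone for each, the correlation was 0.00726 (covariance 0.00747) for LmnB1_6 against mCherry_3 and LmnB1_16 against mCherry_4. It was 0.0199 (covariance 0.0227) the other way round. In the first of these pairings 477 genes were called higher in both and 711 lower in both (266 and 371 for independent lists), and 630 in opposite directions. In the other 856 and 1016 were shared (592 and 679.8 for independent lists), and 1342 were opposite.

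The LmnB1 clones were compared with each other to measure how clones of that construct differ. PLXNA4, a semaphorin receptor gene, was at 256 ± 51.4 in LmnB1_16 and had 0 counts in LmnB1_6, a difference of at least 6268-fold. COL4A5, a basement membrane collagen gene, PGM5, DMD (dystrophin) and the glutamate transporter gene SLC1A1 also had 0 counts in LmnB1_6, and were at least 1091-fold, 728-fold, 600.1-fold and 462-fold higher in LmnB1_16, where they stood at 44.5 ± 3.02, 29.7 ± 2.15, 24.5 ± 0.820 and 18.8 ± 0.942. NKD1, an inhibitor of Wnt signalling, was at 372 ± 38.3 in LmnB1_6 with 1 count in LmnB1_16, and PALM was at 41.8 ± 0.586 with 1 count. FNDC10, TMEM168 and HSD17B2 were at 17.98 ± 2.55, 13.6 ± 0.376 and 11.6 ± 1.05 in LmnB1_6 with 0 counts in LmnB1_16, at least 409-fold, 308-fold and 264-fold higher. The test called 5289 genes, 2734 higher and 2555 lower in LmnB1_16, of which 1627 differed at least 2-fold. HOX genes were lower in LmnB1_16 for 7 of 8 members (median -5.12, camera adjusted p = 5.39e-08, adjusted p = 0.0158 with an estimated correlation), and MHC class I and antigen processing genes were higher for 14 of 15 (median 0.73, camera adjusted p = 2.11e-08, adjusted p = 0.0255 with an estimated correlation). HOXB8 had 0 counts in LmnB1_16, and with it set to 3 counts over that clone the median of the list was still -5.12. The medians of the other lists above with such a gene did not change either, to 2 decimals.

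**Figure D5:**
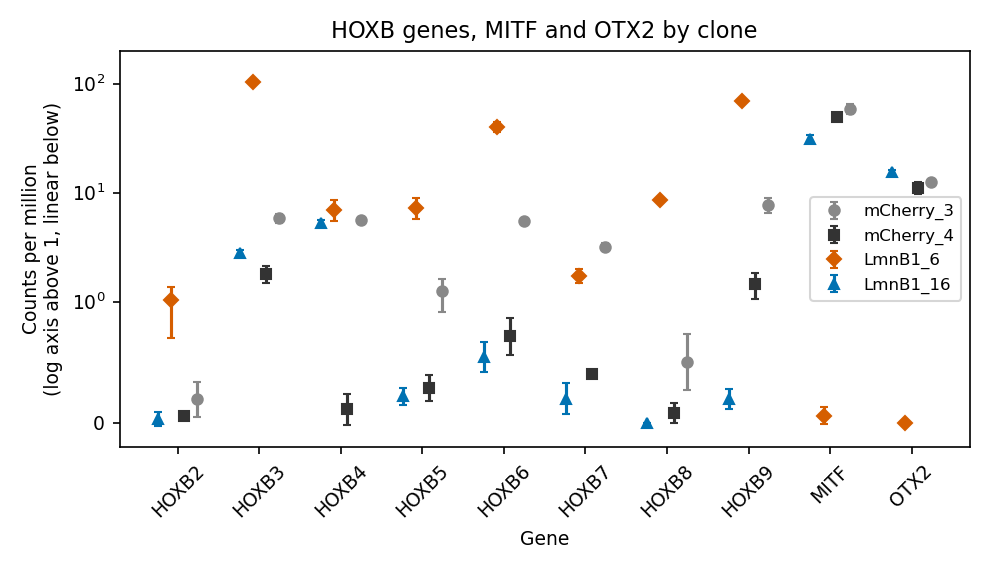
Counts per M of the 8 tested HOXB genes, MITF and OTX2 in each clone (mean and SD, n = 3, axis logarithmic above 1 and linear below). HOXB3, HOXB6 and HOXB9 are highest in LmnB1_6, where OTX2 had 0 counts and MITF was at 0.0590. MITF and OTX2 were chosen after their values were seen.

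The mCherry clones were compared in the same way, as the background of clonal differences without the lamin B1 fusion. GALC, which encodes the lysosomal galactosylceramidase, was at 13.4 ± 1.02 in mCherry_4 with 0 counts in mCherry_3 (at least 362-fold higher), and PTPN3, a tyrosine phosphatase gene, was at 11.1 ± 0.473 in mCherry_3 with 0 counts in mCherry_4 (at least 258-fold higher). SLC2A10, NKD1, ABCA8 and SULF1 were at 8.75 ± 0.736, 6.73 ± 0.660, 4.30 ± 0.382 and 3.43 ± 1.09 in mCherry_4 with 0 counts in mCherry_3. PCSK1N was at 34.01 ± 2.27 in mCherry_3 and 0.0592 ± 0.0693 in mCherry_4. TRIML2, NMU and GBGT1 were at 1.72 ± 0.326, 3.53 ± 0.568 and 4.20 ± 0.412 in mCherry_3 with 0, 1 and 2 counts in mCherry_4. All 32 mitotic genes were higher in mCherry_4 (median 1.01, camera adjusted p = 2.34e-28, adjusted p = 0.106 with an estimated correlation), and 21 of 30 interferon-stimulated genes were lower and 3 higher (median -0.60, camera adjusted p = 7.99e-06, adjusted p = 0.106 with an estimated correlation). HOX genes also differed between the mCherry clones, lower in mCherry_4 for 7 of 8 members and higher for 0. Their median was -2.44 (camera adjusted p = 7.99e-06, adjusted p = 0.073 with an estimated correlation). In mCherry_3, mCherry_4, LmnB1_6 and LmnB1_16 the mean log2 level of the HOX list relative to all libraries was 0.63, -1.79, 2.89 and -1.74. The test called 5752 genes, 3067 higher and 2685 lower in mCherry_4.

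Chromosomes were tested as sets, because clonal lines can differ in copy number. The 1058 tested genes of chromosome 19 were lower in LmnB1_16 than in LmnB1_6 (median log2 fold change -0.14, camera adjusted p = 0.00188) and higher in LmnB1_6 than in the mCherry clones (median 0.14, camera adjusted p = 0.0106). With an estimated correlation camera called 0 chromosomes in either of these comparisons (2 and 1 at an unadjusted p under 0.05), and the adjusted p of chromosome 19 was 0.414 between the LmnB1 clones and 0.472 in LmnB1_6. No chromosome was called between the constructs or between the mCherry clones, with either correlation (0 and 0 at an unadjusted p under 0.05 with an estimated correlation).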

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

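The tests of the core genes against the other pairings of the clones, of LMNB1 against differences between clones, and of the cell cycle lists against a low mCherry_3 level and against library size were chosen only after the result was seen.

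Genes that separate both LmnB1 clones from both mCherry clones numbered 720, and LMNB1 was among them. Differences between clones that have nothing to do with the construct may account for a number of that size, since pairing mCherry_4 and LmnB1_16 against mCherry_3 and LmnB1_6 gave 884. LMNB1 itself is not explained that way, because its smallest log2 fold change over the 4 contrasts was 4.39 and its largest between clones of a construct was 0.93. For the other genes an effect of lamin B1 stays open, as each construct is represented by 2 clones and no clone was measured without its construct.

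Between the constructs 15 of 32 replication genes and 3 of 32 mitotic genes were called higher in the LmnB1 libraries and none lower. Against mCherry_4 alone the median log2 fold change over both lists was 0.11, and against mCherry_3 alone it was 0.80, so a low level in clone mCherry_3 may account for part of the difference. Whether it is the whole cause stays open, since without mCherry_3 camera called the replication list (median 0.16, adjusted p = 0.000142, 3 genes higher) and the mitotic list (median 0.09, adjusted p = 0.0392, 0 genes called) with the preset correlation, and neither with an estimated correlation (adjusted p = 0.769 and 0.769). Shallower libraries of that clone are excluded, since its mean total was 25.6 M counts and that of the other clones 23.9 M. Growth rate and density of the cultures are not given in the sources used here.

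The libraries were also regrouped without regard to their labels. Of 100 splits of the 12 libraries into 6 and 6 (462 are possible), only the real split called as many as 2743 genes. The highest other called 1. The others kept at most 2 of the 4 clones whole, so they show only that libraries of a clone are alike. They cannot tell whether chance differences between clones gave the construct calls. The other pairings that keep clones whole called 1874 and 555 genes, which points to a structure of the samples by clone. For gene lists 46 of 100 splits called as many as the real 8, and the highest other called 13, so chance is not excluded for that count. The other pairings that keep clones whole called 11 and 12 lists. For LmnB1_6 against the mCherry clones 1 of 40 regroupings, drawn from 840, reached 7534 genes, which was the real one. The highest other gave 4604, with the 3 mCherry_3 libraries as the group. Every remaining regrouping mixed libraries of different clones in the group, so this count cannot exclude chance differences between clones either. For LmnB1_16 3 of 40 reached the real 5195, so chance is not excluded by that count. Both of the others had the 3 mCherry_3 libraries as the group (7017 and 5865 genes), so that structure shows here too. Only 3 groupings keep these clones whole, too few to test differences between clones.

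Some designs have too few splits for a share under 0.05. These were the core genes (2 of 3 pairings, real value 720, highest other 884), the mCherry clones (1 of 10 splits, 5752 genes, highest other 1), the LmnB1 clones (1 of 10, 5289 genes, highest other 0) and the chromosomes between the LmnB1 clones (1 of 10, 1 chromosome, highest other 0).

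LmnB1_6 and LmnB1_16 differed for 53 of 95 named genes, in the contrast of these clones (edgeR adjusted p from 1.95e-15 to 0.0386). This is a difference between 2 clones and cannot be assigned to the construct, since the mCherry clones differed at 5752 genes and the LmnB1 clones at 5289. The log2 ratio of LmnB1_16 over LmnB1_6 was below 0 for 26 of them, at LMNB1 -0.24, ZSCAN18 -1.44, APBA2 -1.52, ZNF185 -0.51, TNFSF12 -0.97, CKB -1.76, ZNF331 -0.93, RNF125 -2.81, SNAP25 -3.70, IL17RD -3.75, PCDHA6 -1.43, NUP210 -6.70, ISG15 -0.39, LAMB1 -0.19, VCAN -1.33, SNAI2 -3.95, ARHGEF17 -0.20, PMEPA1 -4.05, ID2 -2.84, LTBP2 -2.53, NDRG1 -0.92, PCDHB14 -1.51, HOXB3 -5.22, RDH10 -0.28, SERPINF1 -1.26 and TUBB3 -0.77. It was above 0 for 27, at POGLUT3 0.84, BGN 0.32, ADGRV1 4.38, LY6E 6.48, PLEKHA6 5.06, ZNF512 6.44, SYNE1 0.82, TNFRSF10B 0.20, GADD45A 0.49, IGFBP7 0.47, HERC5 0.68, HLA-E 0.23, DSP 0.82, KRT8 0.20, CCN1 0.76, F3 1.35, SLC7A11 0.24, PHGDH 0.33, TM7SF2 1.03, H2BC12 0.38, H4C8 1.68, LRAT 2.86, CD68 0.81, CSF1R 1.39, TIE1 0.46, MAP2 0.70 and TNNT1 1.58. LY6E and ZNF512 had 0 counts in LmnB1_6 and NUP210 in LmnB1_16, so the ratios of these genes depend on the prior count and are no bounds.

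The clones also differed for 9 gene lists, with median log2 ratios of LmnB1_16 over LmnB1_6 of p53 targets -0.38, senescence secretory genes 1.78, interferon-stimulated genes 0.51, MHC class I and antigen processing 0.73, TGF-beta targets -0.29, unfolded protein and ATF4 response 0.17, clustered protocadherins -0.75, HOX genes -5.12 and neuronal and glial markers -0.99. With an estimated correlation 2 of these lists were called, MHC class I and antigen processing and HOX genes. Groups of 3 libraries were not tested for single libraries far from the others.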

How the results depend on the processing

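The counts of gene lists without each clone, with either correlation, are tests chosen only after the result was seen. No fold change of a named gene reversed under the alternatives run for single genes, but leaving out a clone was not among these. Single clones did give the other sign for some genes. HOXB3, ID2 and LTBP2, called higher between the constructs, had -0.23, -0.04 and -0.07 in LmnB1_16, and were not called there. NUP210 had -7.46 between the constructs, but its smallest change over the 4 clone contrasts was 0.95. The balance of higher and lower calls between the constructs turned with DESeq2 (1896 and 1845) and without mCherry_4 (2592 and 2366), and that of LmnB1_16 with mCherry_4 alone as the control (1026 and 1385). That of LmnB1_6, nearly even at 3747 and 3787, turned in 5 alternatives. Of the called lists, the median turned for interferon-stimulated genes without mCherry_3 (0.00386) and for MHC class I and antigen processing without LmnB1_6 (0.00966).

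The number of genes called between the constructs moved most. It was 587 at 2-fold or more, 163 with clone as a random effect in limma (consensus correlation 0.618 between libraries of a clone), 7141 with the clone means in the model of 4 clones, and 1673 and 1684 on log2 TPM with 1 and 0.1 added. With counts summed per clone edgeR called 0, with 642 at an unadjusted p under 0.05 and fewer samples to fit, while DESeq2 on all libraries called 3741. Without a clone it was 647 (mCherry_3), 4958 (mCherry_4), 1263 (LmnB1_6) and 4808 (LmnB1_16). Without a library it ran from 1392 to 3078, with the low values for libraries of mCherry_3 (1493, 1495 and 1392) and LmnB1_6 (1567, 1527 and 1828). It stayed within 1.5 times with size factors by relative log expression (2782), no filter (1897), a mean of 1 CPM (2757) and length offsets (1891). Apart from the summed counts and the stricter fold, the cause was not tested.

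The replicate number as a block gave 1648 genes between the constructs. Whether the numbers pair the samples stays open. Over 18 pairs of libraries with the same number, the correlation of residuals ran from -0.0875 to 0.253 (median 0.0613, 5 over 0.1). Pairs with different numbers ran from -0.180 to 0.165. For replicate 3 the values were 0.207, 0.253 and 0.182 among mCherry_4, LmnB1_6 and LmnB1_16. With replicate 3 of mCherry_3 these clones gave 0.0133, -0.0700 and -0.00923.

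Core genes numbered 209 at 1.5-fold or more in all 4 contrasts, 407 with length offsets, and 511 to 711 without a library. The LMNB1 log2 fold change was 4.80 to 6.24 over the alternatives, the highest with length offsets (6.21) and log2 TPM, and 4.80 to 5.01 without a library. With counts summed per clone it was 4.89 with an edgeR adjusted p of 0.778 (range of the other alternatives 2.64e-137 to 6.28e-06). The unadjusted p of LMNB1 in that edgeR test was 0.000247, with 2 residual degrees of freedom. So the summed test did not call even LMNB1, and its 0 calls do not show that the constructs are alike.

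Gene lists called numbered 0 with camera and an estimated correlation (1 at an unadjusted p under 0.05), 1 with fry, 7 to 9 without a library, and 4, 10, 8 and 12 without mCherry_3, mCherry_4, LmnB1_6 and LmnB1_16. Without these clones camera with an estimated correlation called 0, 0, 0 and 1 (2, 4, 3 and 4 at an unadjusted p under 0.05). Chromosome shifts, counted between the constructs and between clones of a construct, numbered 0 with camera and an estimated correlation (0, 0 and 2 at an unadjusted p under 0.05 between the constructs, the mCherry clones and the LmnB1 clones) and 1 to 1 without a library. LmnB1_16 had 2411 genes with mCherry_4 alone as the control. Without a library the counts were 6422 to 8027 for LmnB1_6, 4443 to 5291 for LmnB1_16, 4701 to 6227 for the mCherry clones and 4521 to 5422 for the LmnB1 clones. The cause of these changes was not tested.

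Of the named results, 116 kept their side of the threshold with DESeq2, 117 with size factors by relative log expression and 31 with clone as a random effect, where 66 no longer passed it. With counts summed per clone 8 kept it, all of them genes not called in the main test, and 89 no longer passed. The same 8 are among the 31 with clone as a random effect. DESeq2 gave no adjusted p for 1 gene. The filter on low counts left out 45320 genes, and at this depth a gene with 0 counts in LmnB1_6 is bounded at 0.0408 CPM.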

Other observations

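The test of a gained copy of chromosome 19 was chosen only after the result was seen, as were the values of LmnB1_16 without a library and after removal of a trend, the spreads by which the construct and low expression were judged, the bounds for genes of single clones and the set of zinc finger genes.

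LmnB1_6 stood apart by genes that were nearly silent in it alone. Under 0.5 CPM there and at 5 or more in each of the other clones were 35 genes, against 4, 3 and 1 for mCherry_3, mCherry_4 and LmnB1_16. In the order mCherry_3, mCherry_4, LmnB1_6 and LmnB1_16, CPM are given for the matrix glycoprotein gene RELN (77.9, 109.9, 0.139 and 134), the pigment cell transcription factor genes MITF (58.6, 48.97, 0.0590 and 31.3) and OTX2 (12.6, 11.1, 0 and 15.5), the aminopeptidase gene ANPEP (26.9, 80.5, 0.153 and 49.1) and the kinase gene DAPK1 (70.5, 51.1, 0.0224 and 38.4). The reverse, 5 or more in that clone alone and under 0.5 in the others, held for 13 genes in LmnB1_6 and 1, 1 and 2 in the others, and in LmnB1_6 it held for PDZRN3 (0.0247, 0.484, 60.01 and 0.0448), FLG (0.0731, 0.395, 19.1 and 0.0489) and SALL4 (0.0246, 0.160, 6.18 and 0.106). HOXB4 was nearly silent in mCherry_4 (0.113), while it stood at 5.58, 6.99 and 5.28 in mCherry_3, LmnB1_6 and LmnB1_16. The genes named in this paragraph were chosen after their values were seen. The pigment epithelium list, which holds MITF and OTX2, was not called in LmnB1_6 (3 of 12 higher, 6 lower, camera adjusted p = 0.214).

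The 211 tested zinc finger genes of chromosome 19 had a median log2 fold change of 0.40 in LmnB1_6 (110 higher, 3 lower) and 0.18 in LmnB1_16 (60 and 9), each against the mCherry clones. Between clones of a construct it was 0.26 for mCherry_4 over mCherry_3 (65 and 6) and -0.20 for LmnB1_16 over LmnB1_6 (3 and 39). The 246 zinc finger genes elsewhere had medians of 0.13 and 0.09 in LmnB1_6 and LmnB1_16. Zinc finger genes share sequence, so single members are uncertain.

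The lamina binds gene-poor chromatin, so the hypothesis was tested that genes in gene-sparse regions (at most 10 protein-coding genes within 1 Mb either side, 3346 genes) are lower against gene-dense regions (at least 48, 3073 genes) in cells with more lamin B1. Dense minus sparse, in log2 relative to all libraries, was 0.0582 ± 0.0566, -0.0483 ± 0.0310, 0.0767 ± 0.0173 and -0.0843 ± 0.106 in mCherry_3, mCherry_4, LmnB1_6 and LmnB1_16 (SD, n = 3), and LmnB1_6 lay 0.101 above the mean of the other clones. Of these, mCherry_3 lay close to LmnB1_6. Without chromosome 19 mCherry_3 was the higher, at 0.0748 ± 0.0577 against 0.0534 ± 0.00635 in LmnB1_6. A construct effect shared by both LmnB1 clones was not seen, but with 2 clones of each construct a small one cannot be excluded. LmnB1_16 lay at -0.0892 against the mean of the mCherry clones and at -0.142 (SD 0.120) against the higher, mCherry_3. Without its replicate 2 these values were -0.0281 and -0.0813 (SD 0.0569). After removal of the trend on GC content and length, LmnB1_6 and LmnB1_16 lay at -0.0175 and 0.0256 against the mean of the mCherry clones. LmnB1_16 then lay 0.00924 above the higher mCherry clone. A gained chromosome 19 is argued against (median log2 fold change 0.0872 over 716 other protein-coding genes of it). So is low expression of sparse genes (0.0747 at 10 or more CPM, with a loss of 0.0267, SD 0.00629). GC content and gene length are a candidate explanation, since removal of their trend left -0.0260 for LmnB1_6 against the other clones. That removal would also take away a difference by gene density that follows GC content or length, so it cannot tell these apart.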
